A study of Mus musculus with 4 samples.

How the data were processed

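The series held RNA sequencing of 4 samples of sorted mouse lung airway epithelial cells, 2 from HDM-sensitised mice given an SCD1 inhibitor and 2 from HDM-sensitised mice given DMSO. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a strand-preserving kit (NEBNext Ultra II Directional). Unsensitised mice were not analysed here. The deposited signal values were 1 table of 25124 gene symbols by 4 libraries, with read counts per gene divided by 1 size factor per library. The submitters' processing notes name HOMER, DESeq2 and the mouse build mm10, without versions or the step each was used for. The aligner, the read filters and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies, such as the Scd paralogs, Hspa1a and Hspa1b, or Chil3 and Chil4, are therefore uncertain, and 20 tested genes shared all 4 values with another gene.

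The unit was read from the values. Every value of a library was a whole multiple of 1 smallest step (100% within 0.01 of a whole number), and the inverse steps, 1.03 and 1.01 for the DMSO and 1.05 and 0.953 for the inhibitor libraries, equalled the median-of-ratios size factors of the recovered counts. Division by the step gave 24591122 to 27013663 reads per library. For DMSO replicate 2 the step lies within 1% of 1 (0.991), where a step is hard to tell from rounding by its size alone, so the unit of that library rests on its values being multiples of the step and on its size factor. The recovered reads of all 4 libraries were used in the edgeR and DESeq2 fits alone. At the floor for testing, the counting error of 1 library is 19.7%; PCR copies are not independent molecules, so this covers counting error only. Symbols were matched to GENCODE M21 for coordinates (GRCm38, which is mm10), transcript length and GC content: 24505 by symbol, 139 by an older symbol, and 480 were not matched.

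Values were tested on the scale log2(value + 25.8), where 25.8 is the value that equals 1 CPM at the mean library total, and folds are given on that scale, which makes those of genes with low counts smaller. Genes with a mean of at least 25.8 over the 4 libraries were kept (13810), which left out 11314, of which 7917 were 0 in every library. A linear model was fitted with limma 3.58.1 in R 4.3.3 with an intensity trend (prior degrees of freedom 11.2), with the group as its term and no block, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists, 15 of gene function and 19 of cell type markers, were tested with limma's camera on the same model with a preset correlation between genes of 0.01, adjusted within each kind of list, and again with the correlation estimated and with fry. None of the 34 lists passed with the estimated correlation, against 12 with the preset value, and none had an adjusted directional p of fry under 0.05. Fry's mixed test asks for changes in either direction. Its adjusted p was under 0.05 for cell cycle (0.00252), fatty acid oxidation (0.0151), chaperones (0.0151), cytokines (0.0196) and eicosanoids (0.0196). The same held for NRF2 (0.0288), cholesterol (0.0361), MHC class II (0.0400) and ciliated cells (0.0263), and for no other list. With 2 samples per group, camera with the estimated correlation has little power. The goblet cell list, with all 9 tested markers negative, had an unadjusted p of 0.0480 in it. A list that did not pass there is therefore neither shown to differ nor shown not to. Members were adjusted over all genes and over the list alone. The test, the lists, the gene naming rule and the first set of alternatives were chosen before the data were examined. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

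The genes named were Scd1 to Scd4, Fads1, Fads2, Srebf1 and Fasn, the 12 largest changes in each direction among genes that passed without overlap between groups, up to 4 passing members and at least the 2 of smallest p from each function list, the 3 of smallest p from each marker list that passed, and the most abundant member of each epithelial marker list. A few genes that this rule names are not reported here. Genes named outside this rule, after their values were seen, were Agr2, Muc5ac, Cyp2f2, Gabrp, Sftpd, Aqp5, Elovl1, Fads3, Postn, Rn45s and those of the closing section so described. The samples are not said to come from separate animals, so no p value can be said to measure the spread between mice. Those of single genes rest on the spread between these samples, moderated by that of other genes (prior degrees of freedom 11.2). Those of camera with the preset correlation compare list genes with other genes, so genes and not samples serve as replicates.

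Alternatives tried were the replicate number as a block, other pseudocounts, floors and scalings, a fit without the intensity trend, each library left out in turn (the lone sample being assumed to vary like the other group) and an adjusted p under 0.1. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads and the removal of each library's trend on GC content and transcript length by splines with 5 degrees of freedom. A test of the ciliated share, with genes picked in 1 library of each group and measured in the other 2, was also added then, first with a floor 10 times higher and, after its outcome was seen, with the floor for testing. Other groupings of the samples were not tested, and with 2 samples per group an outlying sample cannot be told from the spread. On simulated counts with the measured means and dispersions, the limma test recovered 49 of 97 genes changed 2-fold (50.5%) and 80 of 100 changed 4-fold. Of 13683 genes tested, it also called 13 unchanged ones, to be set beside the 49 and 80 recovered. The simulation held no GC content trend between libraries. Of 50 simulated lists of unchanged genes, camera passed 0 at an unadjusted p under 0.05, and a list lowered by a log2 value of 0.5 had an unadjusted p of 2.45e-08; simulated genes varied independently, so this does not test the preset correlation.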

Results

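RNA was sequenced from airway epithelial cells that had been isolated from mouse lung by fluorescence-activated cell sorting. The mice were wild-type C57BL/6 animals sensitised with house dust mite (HDM), an aeroallergen used to provoke allergic airway inflammation in mice. They had been given either an inhibitor of stearoyl-CoA desaturase 1 (SCD1), the enzyme that makes monounsaturated from saturated fatty acids, or the vehicle dimethyl sulfoxide (DMSO). Each group held 2 samples, and both groups had received HDM. The values were read counts per gene, scaled by 1 size factor per library. The libraries held 26766159 and 25908728 reads assigned to genes with DMSO and 27013663 and 24591122 with the inhibitor. Between 14797 and 15924 of the 25124 listed genes had a value above 0 in a library. Across genes, the log2 values correlated between the DMSO replicates at r = 0.962, between the inhibitor replicates at r = 0.976 and between libraries of different groups at r = 0.961 to 0.967.

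The comparison asked which airway epithelial transcripts differed between inhibitor-treated and vehicle-treated mice after HDM sensitisation. Genes of mucus-producing goblet cells were lower with the inhibitor as a group (camera, adjusted p = 1.19e-15; adjusted p = 0.573 with an estimated correlation). Fcgbp, which encodes a protein of the mucus gel, had 8162 ± 46.5 normalised reads with DMSO (mean ± SD, n = 2) and 2185 ± 428 with the inhibitor (n = 2), 3.74-fold lower. Fasn, the fatty acid synthase, was 1.70-fold lower, at 24145 ± 876 reads with DMSO and 14236 ± 1431 with the inhibitor (SD, n = 2 each). The surfactant protein gene Sftpc, a marker of alveolar type 2 cells, was 1.56-fold lower. In the other direction, Cep290, which encodes a protein of the ciliary transition zone, was higher, at 3629.8 ± 622 reads against 893 ± 204 (SD, n = 2 each). The membrane-bound mucin Muc4 was 2.98-fold higher, at 7567 ± 1176 reads against 2529 ± 483 (SD, n = 2 each).

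**Figure D1:**
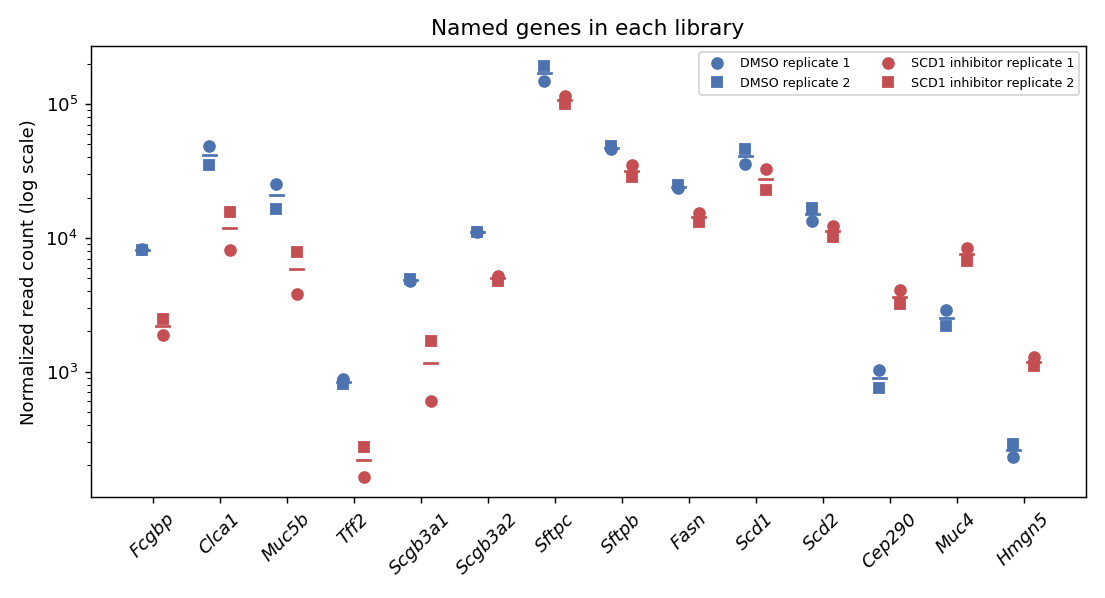
Normalised read counts (vertical axis, log scale) of 14 named genes (horizontal axis) in each of the 4 libraries, with blue for DMSO, red for the SCD1 inhibitor, circles for replicate 1, squares for replicate 2 and short bars for the group means. For Fcgbp both DMSO libraries lie near 8162 and the inhibitor libraries at 1882 and 2487, while for Scd1 the DMSO libraries at 35792 and 46592 lie close to the inhibitor libraries at 32588 and 23006.

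Of 13810 genes tested with limma, 247 passed at a Benjamini-Hochberg adjusted p under 0.05, of which 188 were higher and 59 lower with the inhibitor, and 1944 had an unadjusted p under 0.05. The genes that rose had a median log2 fold change of 0.79 and reached 4.27-fold, and those that fell had a median of -0.80 and reached 5.49-fold. In 6200 genes, 44.9% of those tested, the values of the groups did not overlap, where chance gives 33.3% with 2 samples against 2. Genes are not independent of each other, so the error of this share is not known and the gap shows no effect of treatment by itself. The number of calls rested on the model of the spread: edgeR on the recovered reads called 7 genes higher and 3 lower of 15299 tested (1862 at an unadjusted p under 0.05), limma without its intensity trend called 0 (1423 at an unadjusted p under 0.05), and DESeq2 called 331 higher and 146 lower. It also rested on single libraries, with 616 higher and 179 lower without DMSO replicate 1, 240 and 115 without DMSO replicate 2, 0 and 5 without SCD1 inhibitor replicate 1, and 3 and 12 without SCD1 inhibitor replicate 2. A fit without 1 library takes its spread from the other group's pair alone. The DMSO pair, used without an inhibitor library, differed more (SD of log2 difference 0.581) than the inhibitor pair (0.454). A call can thus end without a smaller log2 fold change, as for Fasn without SCD1 inhibitor replicate 1 (-0.87, against -0.76 with all libraries). All 188 and all 59 genes that passed had no overlap between groups. The naming rule also asked this of the largest changes, so it is no added support for the 37 named genes that passed. Of these, those that still passed without SCD1 inhibitor replicate 1 were Fcgbp, Clca1, Scgb3a1 and Scgb3a2, and 12 still passed without SCD1 inhibitor replicate 2.

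The transcript of the inhibited enzyme, Scd1 (chromosome 19, 44394455 to 44407879, minus strand, mm10), was abundant in all 4 libraries. It had 41192 ± 7637 normalised reads with DMSO and 27797 ± 6776 with the inhibitor (SD, n = 2 each), a log2 fold change of -0.58 ± 0.16 (SE) that did not pass limma's test over all genes (adjusted p = 0.0983). Its paralog Scd2, on the same chromosome at 44293674 to 44306864, had 15113 ± 2417 and 11258 ± 1524 reads and a log2 fold change of -0.42 ± 0.13 (adjusted p = 0.155). The log2 fold changes of Scd1 and Scd2 depended on the library left out. They were -0.77 and -0.58 without DMSO replicate 1 and -0.39 and -0.26 without DMSO replicate 2. The values were -0.83 and -0.56 without SCD1 inhibitor replicate 1 and -0.33 and -0.28 without SCD1 inhibitor replicate 2. With DESeq2, Scd2 passed (adjusted p = 0.0205) and Scd1 did not (adjusted p = 0.368). Scd3 was low, with means of 58.3 and 59.2 reads (log2 fold change 0.022 ± 0.56, adjusted p = 0.991), and Scd4 lay below the floor for testing, with at most 28.7 reads. An inhibitor acts on the enzyme, so these transcripts do not check the treatment labels.

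Fatty acid synthesis genes were lower with the inhibitor as a group. Of 22 tested members of the fatty acid synthesis and desaturation list, 18 had a negative log2 fold change, and the list median was -0.32, 1.25-fold lower (limma camera, adjusted p = 2.28e-06; adjusted p = 0.451 with an estimated correlation). Fasn (chromosome 11, 120805846 to 120824547, minus strand) was the 1 member that fell in the test over all genes, with a log2 fold change of -0.76 ± 0.11 (SE, adjusted p = 0.00454). Adjusted over the list alone, 6 members were lower: Fasn, Acaca, Elovl1, Scd1, Scd2 and Fads3. Acaca, which makes the malonyl-CoA used by Fasn, had a log2 fold change of -0.58 ± 0.15 (adjusted p = 0.0681 over all genes and 0.0263 without DMSO replicate 2), and the desaturases Fads1 and Fads2 and the lipogenic transcription factor Srebf1 had values of -0.35, -0.64 and -0.25 (adjusted p = 0.379, 0.377 and 0.331). Fads1 and Fads2 had -0.58 and -1.06 without SCD1 inhibitor replicate 1 and -0.12 and -0.23 without SCD1 inhibitor replicate 2. The call of Fasn ended without SCD1 inhibitor replicate 1 (-0.87, adjusted p = 0.0727) and without SCD1 inhibitor replicate 2 (-0.66, adjusted p = 0.239), and with edgeR (-0.77, adjusted p = 0.0626).

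Cholesterol synthesis genes were also lower as a group, with 21 of 24 tested members negative, a median log2 fold change of -0.29 and camera's adjusted p = 0.000223 (adjusted p = 0.451 with an estimated correlation). None of its members passed, over all genes or adjusted over the list alone. Srebf2, the main regulator of sterol synthesis, had -0.31 ± 0.10 (SE, adjusted p = 0.188). The fatty acid oxidation and PPAR target list did not pass camera's test (26 genes, median -0.085, adjusted p = 0.513). Adjusted over the list alone, Cpt2, an enzyme of mitochondrial fatty acid import, was lower (-0.83) and Ppargc1a, a coactivator of oxidative metabolism, higher (0.60). Both lipid synthesis lists kept their call without each of the 4 libraries in turn. Markers of alveolar type 2 cells, which make surfactant lipid, were lower in the same libraries, with a list median of -0.53 (adjusted p = 0.573 with an estimated correlation).

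Goblet cell markers were the list furthest from 0 among all those tested. All 9 were negative and 6 fell in the test over all genes, with a list median of -1.61, 3.06-fold lower (camera, adjusted p = 1.19e-15; adjusted p = 0.573 with an estimated correlation). Fcgbp (chromosome 7, 28071236 to 28120862, plus strand) fell, with a log2 fold change of -1.90 ± 0.14 (SE, adjusted p = 5.75e-05). Clca1, a secreted protein of goblet cells (chromosome 3, 145003817 to 145032776, minus strand), had 41828 ± 9276 reads with DMSO and 11805 ± 5231 with the inhibitor (SD, n = 2 each; adjusted p = 0.00163). The gel-forming mucin Muc5b fell 3.69-fold (adjusted p = 0.00362), the trefoil peptide Tff2 3.64-fold (adjusted p = 0.0102) and the secreted Bpifb1 3.06-fold (adjusted p = 0.0110). The sixth was Agr2, a disulfide isomerase needed for mucin folding (-1.49, adjusted p = 0.0476), and the other gel-forming mucin of the airway, Muc5ac, had -0.80 ± 0.23 (adjusted p = 0.121); both were named after their values were seen. Adjusted over the list alone, all 9 were lower. The list kept its call without each library in turn, with medians from -2.10 to -1.36. Without SCD1 inhibitor replicate 1 the calls of Muc5b (-1.36, adjusted p = 0.0727), Tff2 (-1.53, adjusted p = 0.208) and Bpifb1 (-0.98, adjusted p = 0.0702) ended, and that of Tff2 ended also without SCD1 inhibitor replicate 2 (-2.20, adjusted p = 0.0676). Agr2 lost its call without either inhibitor replicate and without DMSO replicate 2 (-1.09, adjusted p = 0.184).

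The list of IL-13 responsive and mucus genes had a median of -0.52 over 21 tested genes (adjusted p = 2.28e-06; adjusted p = 0.451 with an estimated correlation), with 6 genes lower over all genes tested and 9 lower and 1 higher adjusted over the list alone. The 6 were the goblet cell genes just described, and 8 of the 21 genes stood on both lists. The 13 members that were not goblet cell markers had a median of 0.034, with 7 positive and 6 negative, and none passed over all genes tested. Postn had the highest of these values (log2 fold change 2.08 ± 0.72, SE, limma adjusted p = 0.200). The list median was -0.85 without DMSO replicate 2. Of the other genes that fell most over all genes tested, the antimicrobial lectin Reg3g fell 2.90-fold (log2 fold change -1.53 ± 0.17, SE, adjusted p = 0.000931), the iron-binding lactoferrin gene Ltf 4.07-fold (adjusted p = 0.0263) and the peptidoglycan recognition protein gene Pglyrp1 3.24-fold (adjusted p = 0.0325). Ern2, the endoplasmic reticulum stress sensor of mucous epithelia, had the lowest log2 fold change of all genes that passed, -2.46 ± 0.54 (adjusted p = 0.0385), at 184 ± 45.8 and 12.2 ± 6.46 reads. These 4 calls ended without SCD1 inhibitor replicate 1 (adjusted p = 0.0596, 0.176, 0.446 and 0.371), and the log2 fold change of Ltf went from -2.03 to -1.08. The calls of Pglyrp1 and Ern2 also ended without DMSO replicate 1 (adjusted p = 0.0789 and 0.0624) and without SCD1 inhibitor replicate 2 (adjusted p = 0.280 and 0.406), where the value of Ltf was -2.97.

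Club cell and alveolar type 2 cell markers were lower as well. All 12 club cell markers were negative and 5 fell (median -0.49, adjusted p = 1.08e-11; adjusted p = 0.573 with an estimated correlation). They were the secretoglobins Scgb3a2 (2.22-fold, log2 fold change -1.15 ± 0.11, adjusted p = 0.000365) and Scgb3a1 (4.65-fold, adjusted p = 0.00454), the secreted defence protein Bpifa1 (5.45-fold, adjusted p = 0.0271), and Cyp2f2 and Gabrp, named after their values were seen. The most abundant club cell marker, the secretoglobin Scgb1a1, had 276340.0 ± 48769 and 247953 ± 119492 reads (log2 fold change -0.23 ± 0.24, adjusted p = 0.729), and its value was -0.75 without SCD1 inhibitor replicate 1 and 0.28 without SCD1 inhibitor replicate 2. Of 12 alveolar type 2 markers, 10 were negative and 5 fell (median -0.53, adjusted p = 4.52e-09; adjusted p = 0.573 with an estimated correlation). They were the surfactant protein genes Sftpc (170409 ± 29829 against 108330.0 ± 10604 reads, adjusted p = 0.0345), Sftpb (1.49-fold, adjusted p = 0.0286) and, named after its value was seen, Sftpd, the lipid transporter Abca3 (1.43-fold, adjusted p = 0.0248) and the lysozyme gene Lyz2 (1.54-fold, adjusted p = 0.0205). Cyp2f2, Gabrp and Sftpd lost their calls without either inhibitor replicate (adjusted p from 0.102 to 0.770). Adjusted over the list alone, 7 club cell and 8 alveolar type 2 markers were lower. Both lists kept their calls without each library in turn, and the club cell median was -0.81 without SCD1 inhibitor replicate 1. Without SCD1 inhibitor replicate 1 the calls of Sftpc, Sftpb, Abca3 and Lyz2 ended, though their log2 fold changes lay further below 0. They were -0.75, -0.71, -0.56 and -0.74, against -0.65, -0.57, -0.52 and -0.62 with all libraries. The call of Bpifa1 ended too, at -1.24, while Scgb3a1 had -1.49. Sftpc lost its call also without DMSO replicate 2 (adjusted p = 0.0751). Without SCD1 inhibitor replicate 2 the calls of Sftpc, Sftpb, Abca3 and Lyz2 ended with log2 fold changes of -0.55, -0.43, -0.48 and -0.50. Bpifa1 then had -3.66 and Scgb3a1 -2.94, and the medians were -0.30 for the club cell and -0.35 for the alveolar type 2 list.

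Basal cell markers had a median of -1.30 over 5 tested genes, all negative (adjusted p = 0.000903; adjusted p = 0.678 with an estimated correlation). The basal keratins Krt5 (-1.30 ± 0.36, adjusted p = 0.0972) and Krt15 (-1.50 ± 0.41, adjusted p = 0.0921) and the water channel Aqp3 (-1.58 ± 0.41, adjusted p = 0.0752) did not pass over all genes and passed adjusted over the list alone. Krt5 and Aqp3 passed over all genes without DMSO replicate 2 (adjusted p = 0.0152 and 0.0334) and with DESeq2 (0.0311 and 0.0292), and Krt15 without SCD1 inhibitor replicate 2 (0.00224). Their values were smaller without SCD1 inhibitor replicate 1, for Krt5 -0.73, Krt15 -0.55 and Aqp3 -0.85 (adjusted p = 0.677, 0.577 and 0.619). The inhibitor libraries differed among themselves in these markers, with a median log2 difference of replicate 1 minus replicate 2 of -1.49, and in the goblet cell markers, with -0.52. The basal list lost its call without SCD1 inhibitor replicate 1 (-0.56, adjusted p = 0.0980) and had -2.05 without SCD1 inhibitor replicate 2. Ciliated cell markers had a median of 0.16 over 12 genes (adjusted p = 0.0162; adjusted p = 0.573 with an estimated correlation). Ccdc39, which is needed to assemble the ciliary axoneme, was the 1 member that rose (2.68-fold, log2 fold change 1.42 ± 0.16, adjusted p = 0.00140; adjusted p = 0.0727 without SCD1 inhibitor replicate 1 and 0.0676 without SCD1 inhibitor replicate 2). The dynein gene Dnah5 (0.37, adjusted p = 0.161), Ccdc153 (0.34, adjusted p = 0.224) and the most abundant marker Sec14l3 (-0.085, adjusted p = 0.819) did not pass over all genes, though Dnah5 did without DMSO replicate 1 (adjusted p = 0.00821) and Ccdc153 without DMSO replicate 2 (0.0166). The ciliated list lost its call without DMSO replicate 1 (0.0042, adjusted p = 0.361) and without SCD1 inhibitor replicate 2 (0.15, adjusted p = 0.0521), and had 0.28 without DMSO replicate 2.

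The markers common to epithelial cells (8 genes, median 0.15, adjusted p = 0.785; Cd24a 0.28), to alveolar type 1 cells (9 genes, median -0.11, adjusted p = 0.119; Cldn18 -0.11) and to neuroendocrine cells, tuft cells and ionocytes (8 genes, median 0.057, adjusted p = 0.876) did not pass as lists. Aqp5, a water channel on the alveolar type 1 list that was named after its value was seen, fell (log2 fold change -0.85 ± 0.16, adjusted p = 0.0203; adjusted p = 0.353 without SCD1 inhibitor replicate 1 and 0.416 without SCD1 inhibitor replicate 2). The alveolar type 1 list passed without SCD1 inhibitor replicate 2 (median -0.21, adjusted p = 0.0387).

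**Figure D2:**
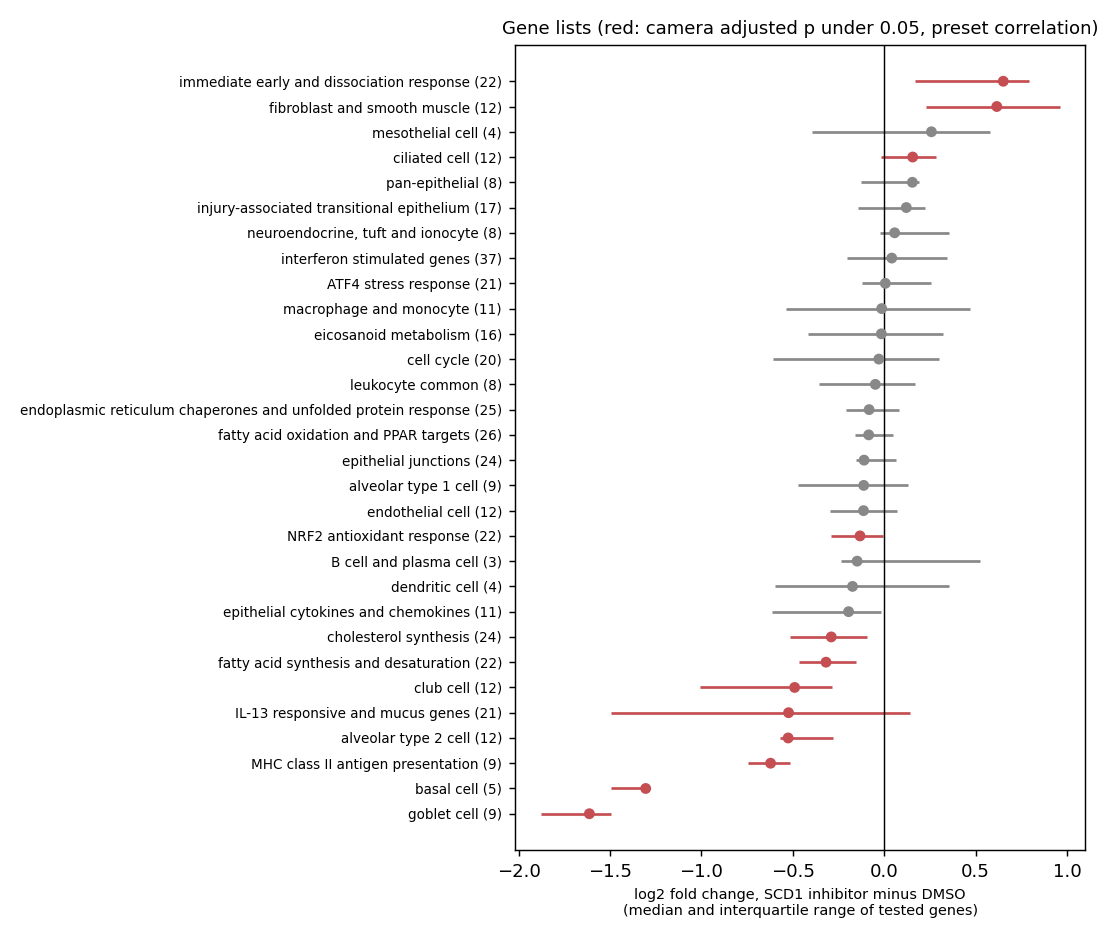
Log2 fold changes, SCD1 inhibitor minus DMSO (horizontal axis), of the gene lists with at least 3 tested genes (vertical axis, number of tested genes in brackets). Points are medians, lines are interquartile ranges and red marks an adjusted p under 0.05 by camera with the preset correlation. The goblet cell list has the lowest median, -1.61, and the immediate early list the highest, 0.65.

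Antigen presentation genes were lower as a group. Of 9 genes of the MHC class II list 7 were negative (median -0.62, adjusted p = 0.00142; adjusted p = 0.451 with an estimated correlation), and Cd74, the invariant chain that accompanies class II molecules, fell (log2 fold change -0.74 ± 0.13, adjusted p = 0.0162), while the class II chain H2-Ab1 had -0.52 ± 0.20 (adjusted p = 0.249). Leukocyte common markers had a median of -0.048 (8 genes, adjusted p = 0.814). The MHC class II list lost its call without DMSO replicate 2 (-0.45, adjusted p = 0.0747) and had -0.40 without SCD1 inhibitor replicate 2. Cd74 lost its call without either inhibitor replicate, with a log2 fold change of -0.82 (adjusted p = 0.213) without replicate 1 and -0.67 without replicate 2. The NRF2 antioxidant list had a median of -0.13 over 22 genes (adjusted p = 0.0266; adjusted p = 0.451 with an estimated correlation), with no member past the test. Pgd, of the pentose phosphate pathway, had -0.42 (adjusted p = 0.108, and 0.0435 without DMSO replicate 2) and the glutathione conjugate exporter Abcc1 -0.47 (adjusted p = 0.132). That list lost its call without DMSO replicate 2 (-0.043, adjusted p = 0.441) and without SCD1 inhibitor replicate 1 (-0.11, adjusted p = 0.0950).

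Immediate early and dissociation response genes, which respond to handling of cells, were higher as a group, with a median of 0.65 over 22 genes (adjusted p = 0.00417; adjusted p = 0.763 with an estimated correlation). The transcription factor Klf6 (0.70 ± 0.15, adjusted p = 0.0315) and the chaperone Hsp90aa1 (0.63 ± 0.15, adjusted p = 0.0463) rose, whereas the heat shock genes Hspa1a (-1.25 ± 0.29, adjusted p = 0.0473) and Hspa1b (-0.96 ± 0.20, adjusted p = 0.0315), near-identical copies whose reads cannot be surely separated, fell. With each library's GC content and length trend removed, these 4 calls ended (Klf6 0.40, adjusted p = 0.184; Hsp90aa1 0.60, 0.0870; Hspa1a -1.11, 0.123; Hspa1b -0.81, 0.0907). The DMSO libraries differed from each other in this list by a median log2 difference of 1.04 (replicate 1 minus replicate 2). The list median was -0.007 without DMSO replicate 2 (adjusted p = 0.462) and 0.31 without SCD1 inhibitor replicate 1 (adjusted p = 0.0950), against 1.15 without DMSO replicate 1. All 4 of these genes lost their call without either inhibitor replicate, Hspa1a also without DMSO replicate 1 (adjusted p = 0.101) and Hsp90aa1 also without DMSO replicate 2 (0.41, adjusted p = 0.0930), where Klf6 had 0.43. The ribosomal RNA precursor Rn45s, named after its values were seen, had 24308 and 77528 normalised reads with DMSO and 19478 and 24966 with the inhibitor.

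The remaining function lists did not pass camera's test with the preset correlation. They were ATF4 stress response (21 genes, median 0.0064, adjusted p = 0.934; Atf3 1.14, Vldlr 0.53), endoplasmic reticulum chaperones (25 genes, median -0.082, adjusted p = 0.270), epithelial cytokines (11 genes, median -0.19, adjusted p = 0.125; Cx3cl1 -0.69, Cxcl16 -0.66) and interferon stimulated genes (37 genes, median 0.042, adjusted p = 0.934; Eif2ak2 0.67, Ifih1 0.65). The others were eicosanoid metabolism (16 genes, median -0.016, adjusted p = 0.554; Ephx1 -0.38, Ptges -1.18), cell cycle (20 genes, median -0.029, adjusted p = 0.934; Cenpf 2.04, Mcm5 -1.83), epithelial junctions (24 genes, median -0.11, adjusted p = 0.127; Tjp1 0.41, Jup -0.35) and injury-associated transitional epithelium (17 genes, median 0.12, adjusted p = 0.586; Anxa1 0.33, Krt19 -0.24). None of the genes in brackets passed the test. Atf3 had 2.53 (adjusted p = 1.22e-06) without DMSO replicate 1 and -0.25 without DMSO replicate 2, and Eif2ak2, Ifih1 and Jup passed without DMSO replicate 1 (adjusted p = 0.0366, 0.0152 and 0.0240). On the chaperone list, Hsp90b1, the endoplasmic reticulum form of Hsp90, rose (0.58 ± 0.11, adjusted p = 0.0203) and Ern2 fell. Both calls ended without either inhibitor replicate (Hsp90b1 adjusted p = 0.198 and 0.512, Ern2 0.371 and 0.406), and that of Ern2 also without DMSO replicate 1 (0.0624). They also ended with the GC content and length trend removed (Hsp90b1 0.35, adjusted p = 0.169; Ern2 -2.32, adjusted p = 0.0787). Without DMSO replicate 1 the cytokine list passed (median -0.64, adjusted p = 0.0479). Mean and test differed in sign from the median or from each other for the interferon list (mean 0.014, test lower) and the cell cycle list (mean 0.0045, test lower).

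Markers of cells outside the epithelium varied between libraries of 1 group. The fibroblast and smooth muscle list was higher with the inhibitor (12 genes, median 0.62, adjusted p = 0.0294; adjusted p = 0.926 with an estimated correlation), with 11 positive members and none past the test. The collagens Col1a1 and Col3a1 had 0.95 and 0.98 and the pericyte receptor Pdgfrb 1.44 (adjusted p = 0.299, 0.246 and 0.330; 0.0152, 0.00150 and 0.00559 without DMSO replicate 2). Its median difference between the DMSO libraries was -1.48 (replicate 1 minus replicate 2), and the list median was -0.17 without DMSO replicate 1 (adjusted p = 0.361) and 0.71 without SCD1 inhibitor replicate 1 (adjusted p = 0.0969), against 1.34 without DMSO replicate 2. The endothelial list did not pass (12 genes, median -0.11, adjusted p = 0.578), but the DMSO libraries differed in it by -2.30, and it passed in opposite directions without DMSO replicate 1 (-1.40, adjusted p = 1.48e-08) and without DMSO replicate 2 (1.24, adjusted p = 0.000580). The mesothelial list (4 genes, median 0.26, mean -0.073, test lower, adjusted p = 0.785) held 1 gene that fell, Msln (log2 fold change -1.58 ± 0.34, adjusted p = 0.0381; adjusted p = 0.0505 without DMSO replicate 1 and 0.481, with -0.95, without SCD1 inhibitor replicate 1). None of the leukocyte and blood cell lists passed: macrophages and monocytes (11 genes, median -0.014, test higher, adjusted p = 0.953), dendritic cells (4 genes, -0.17, adjusted p = 0.927) and B cells (3 genes, median -0.15, mean 0.24, test higher, adjusted p = 0.927). Eosinophil and mast cell markers (2 tested genes, -0.57, adjusted p = 0.578), neutrophil (1 gene, 0.28, adjusted p = 0.876), T cell (1 gene, 0.32, adjusted p = 0.785) and erythroid markers (1 gene, -0.061, adjusted p = 0.927) were mostly below the floor.

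Of the genes that passed, the 12 with the largest increases stood on none of the lists. Log2 fold changes of genes that did not pass reached 2.27, and Cenpf, on the cell cycle list, had 2.04. The largest of the 12 were Hmgn5, a nucleosome-binding protein gene (4.27-fold, log2 fold change 2.09 ± 0.25, adjusted p = 0.00163), the condensin subunit Smc4 (4.17-fold, adjusted p = 0.00454) and Cep290 (chromosome 10, 100487558 to 100574840, plus strand, adjusted p = 0.000365). The log2 fold change of Cep290 lay between 1.77 and 2.23 with each library left out in turn. The nuclear pore protein gene Tpr rose 3.38-fold (adjusted p = 0.00136), the cohesin loader Nipbl 3.04-fold (adjusted p = 0.00825) and Muc4 (chromosome 16, 32735886 to 32782391, plus strand) by a log2 fold change of 1.58 ± 0.15 (adjusted p = 0.000365). Ankrd12, the centriolar Cntln, the autophagy gene Rb1cc1 and the zinc finger genes Zfp946 and Zfp74 were also among the 12 largest increases, at 2.89, 2.83, 2.75, 3.27 and 2.81-fold. Genes of the 12 that passed with edgeR included Hmgn5, Smc4, Cep290, Muc4 and Rb1cc1 (adjusted p = 0.0397, 0.0460, 0.0322, 0.0392 and 0.0401). Without SCD1 inhibitor replicate 1 none of the 12 passed (adjusted p = 0.0596 for Cep290 and 0.0596 for Muc4). Without SCD1 inhibitor replicate 2 Cep290 (adjusted p = 0.00807) and Muc4 (0.00727) did, and without DMSO replicate 2 the log2 fold change of Nipbl went from 1.61 to 1.07 and that of Ankrd12 from 1.53 to 1.0.

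Transcripts of the genes that rose were poorer in G and C than those of other genes. Their median GC content was 43.6% and their median length 3346 bp, against 54.7% and 2002 bp for the genes that fell and 51.2% and 2231 bp for all tested genes. Across 13709 genes, which are not independent replicates, the log2 fold change correlated with GC content at Spearman's rho = -0.37. The difference between the DMSO replicates did so at -0.19 and that between the inhibitor replicates at -0.036. Among the genes of lowest GC content, 1 of 10 equal bins, the median log2 difference was 0.32 between groups and 0.19 between DMSO replicates 1 and 2. With each library's trend on GC content and length removed, 61 genes were higher and 27 lower, of which 59 and 23 were among the 188 and 59 above. All 188 kept a positive value, and their median log2 fold change went from 0.79 (median SE 0.15) to 0.58 (median SE 0.14). Of the 37 named genes that had passed, 23 still did, and Abca3, Bpifa1, Ern2, Hsp90aa1, Hsp90b1, Hspa1a, Hspa1b, Klf6, Ltf, Msln, Pglyrp1, Sftpb, Zfp74 and Zfp946 did not, nor did Cyp2f2, Sftpd and Aqp5. Some of these values hardly moved and others shrank (Ltf -2.03 to -2.03, Bpifa1 -2.45 to -2.42, Pglyrp1 -1.70 to -1.59, Msln -1.58 to -1.46, Abca3 -0.52 to -0.44, Sftpb -0.57 to -0.44, Zfp74 1.49 to 1.37 and Zfp946 1.71 to 1.23). The chaperone list (median -0.14, adjusted p = 0.0175) and the cytokine list (median -0.17, adjusted p = 0.0185) then passed, the NRF2 list did not (median -0.036, adjusted p = 0.0676), and the other 11 lists that had passed kept their calls.

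**Figure D3:**
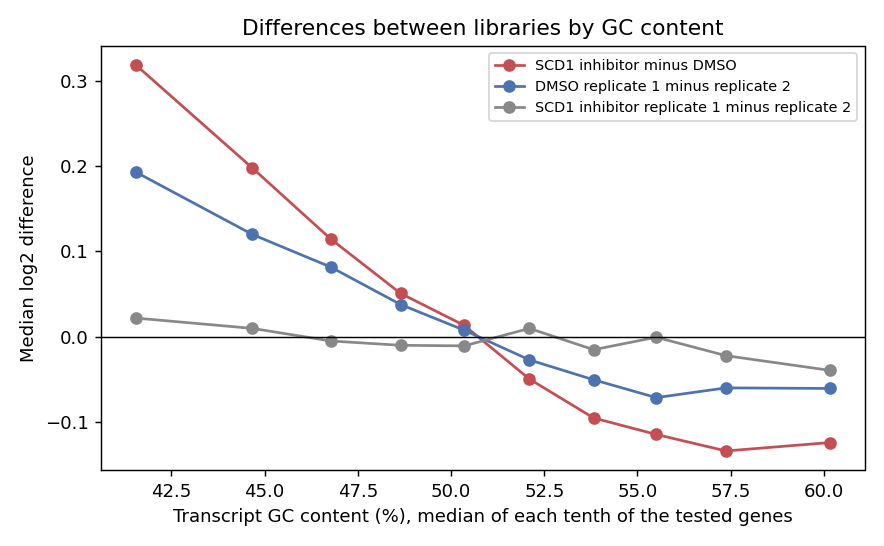
Median log2 difference (vertical axis) of the tested genes in 10 equal bins of transcript GC content (horizontal axis, median percent of each bin), for the SCD1 inhibitor minus DMSO (red), DMSO replicate 1 minus replicate 2 (blue) and SCD1 inhibitor replicate 1 minus replicate 2 (grey). The difference between groups goes from 0.32 in the lowest bin to -0.12 in the highest, and that between the DMSO replicates from 0.19 to -0.061.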

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

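The edgeR, DESeq2 and GC content and length alternatives were chosen after seeing the data, and the others were not. With the replicate block, 469 genes were higher and 205 lower, and Scd1 (-0.58, adjusted p = 3.84e-04) and Scd2 (-0.42, adjusted p = 0.0136) passed. The 2 replicate numbers were not shown to pair samples (correlation of the replicate differences 0.0734). The block leaves fewer degrees of freedom, so its p values rest more on the spread of other genes. Its smallest adjusted p was 2.73e-23, against 5.75e-05 for Fcgbp in limma's fit without the block. The log2 fold changes of Scd1 and Scd2 were those of that fit, so these calls are no added evidence for them. With the block, further named genes that had not passed did so, among them Acaca, Krt5 and Aqp3, and no named gene or list lost its call. With a pseudocount a factor of 10 lower, 139 genes were higher and 37 lower. Without a filter on low values, 51 were higher and 13 lower. With a floor 10 times higher, the fibroblast list (0.28, adjusted p = 0.183) did not pass, the mesothelial list had -1.58 (adjusted p = 0.0456) with Msln its 1 tested gene, and 5 lists (B cells, dendritic cells, neutrophils, eosinophils and erythroid cells) had no tested gene. With no intensity trend, limma called 0 genes higher and 0 lower (1423 at an unadjusted p under 0.05), and 4 lists no longer passed: NRF2 (-0.13, adjusted p = 0.0830), immediate early (0.65, adjusted p = 0.198), ciliated (0.16, adjusted p = 0.172) and fibroblast (0.62, adjusted p = 0.148). At an adjusted p under 0.1, 305 genes were higher and 122 lower. With the GC content and length trend removed, 61 were higher and 27 lower, and NRF2 (-0.036, adjusted p = 0.0676) did not pass. With edgeR on the recovered reads, 7 were higher and 3 lower, and the fibroblast list had 0.58 (adjusted p = 0.117). With DESeq2, 331 were higher and 146 lower, and Scd2 passed (-0.42, adjusted p = 0.0205). Of the 34 named genes that had passed and had an adjusted p with DESeq2, 31 kept their calls. Bpifa1 (-2.01, adjusted p = 0.302), Bpifb1 (-1.49, 0.144) and Ltf (-1.78, 0.292) lost theirs. Lists were not run with it.

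With an estimated correlation, 0 function lists and 0 marker lists passed, against 6 and 6 with the preset value: fatty acid synthesis -0.32, cholesterol -0.29, IL-13 and mucus -0.52, NRF2 -0.13 and MHC class II -0.62 (adjusted p = 0.451 each), immediate early 0.65 (0.763), club -0.49, goblet -1.61, ciliated 0.16 and alveolar type 2 -0.53 (0.573 each), basal -1.30 (0.678) and fibroblast 0.62 (0.926).

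Without each library in turn, the genes higher ranged from 0 (without SCD1 inhibitor replicate 1, 574 at an unadjusted p under 0.05) to 616 (without DMSO replicate 1), those lower from 5 to 179 (the same libraries) and the function lists past the test from 3 (without DMSO replicate 2) to 7 (without DMSO replicate 1). Scd1 ranged from -0.83 to -0.33 and Scd2 from -0.58 to -0.26. The list medians ranged from -0.19 to -0.043 for NRF2, -0.82 to -0.40 for MHC class II, -0.0070 to 1.15 for immediate early, 0.0042 to 0.28 for ciliated, -2.05 to -0.56 for basal, -0.17 to 1.34 for fibroblast and -1.40 to 1.24 for endothelial genes. Of 37 named genes that passed, 33 still did without DMSO replicate 1, 35 without DMSO replicate 2, 4 without SCD1 inhibitor replicate 1 and 12 without SCD1 inhibitor replicate 2. The same count was 23 with the GC and length trend removed and 9 with edgeR. Over all results and alternatives, 1434 values had the same outcome, with counts that stayed within 1.5 times included. Of the 1434, 871 had passed neither in the main fit nor in the alternative, and 46 of the 871 changed sign. Another 203 values no longer passed, 54 newly passed and 25 counts moved by more than 1.5 times. A further 4 values reversed, none of them a named gene. The cause was not tested.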

Other observations

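The genes and groups of this paragraph and the next were chosen after their values were seen. Among the 188 genes that were higher, 12 had symbols of families named for cilia and centrosomes (Cfap, Dnah, Ift or Cep with a number), 6.38% of them against 0.681% of all tested genes (94 of 13810). The families were chosen because such genes stood among those higher, so no test of this share is given. The 12 were Cep126, Cep290, Cep83, Cfap36, Cfap43, Cfap44, Cfap47, Cfap53, Cfap58, Dnah12, Ift74 and Ift81. With the GC and length trend removed, 6 of 61 were of these families. Of the 94 family members, 71 had a positive log2 fold change, with a median of 0.21, and the ciliated marker list had a median of 0.16. These values are from the fit with the GC and length trend left in. Tested genes in the bin of lowest GC content (median 41.6%) had a median log2 difference between groups of 0.32. Those in the next bin (44.7%) had 0.20. The family median was not measured with the trend removed, so it cannot be told apart from the trend. The ciliated marker list had 0.15 with the trend removed. Large centrosomal scaffold genes outside these families were higher too, Akap9 by a log2 fold change of 1.31 ± 0.16 (SE, limma adjusted p = 0.00197) and Pcm1 by 1.29 ± 0.17 (adjusted p = 0.00281). Without SCD1 inhibitor replicate 1, limma called 0 genes higher (574 at an unadjusted p under 0.05), so these calls ended. Without SCD1 inhibitor replicate 2, Cep290 was the only gene of the 12 that kept its call. The calls of Akap9 and Pcm1 ended there as well, with log2 fold changes of 1.32 and 1.30.

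Several secretory and metabolic genes were lower as well. The iron transport gene Trf had a log2 fold change of -1.23 ± 0.16 (adjusted p = 0.00301), the cartilage matrix gene Chad -1.49 ± 0.19 (adjusted p = 0.00253), the lipid carrier Apoe -0.89 ± 0.16 (adjusted p = 0.0161), the complement gene C3 a 1.99-fold lower value (adjusted p = 0.0203) and the chitinase-like Chil1 -0.71 (adjusted p = 0.0203). The xenobiotic enzymes Cyp2a5 and Cyp2f2 had -0.73 and -0.65 (adjusted p = 0.0173 and 0.0345), and the hypoxia-responsive factor Epas1 -0.62 (adjusted p = 0.0110). The metallothioneins Mt1 (0.57, adjusted p = 0.0450) and Mt2 (0.93, adjusted p = 0.0391) and the long noncoding RNA Neat1 (0.76, adjusted p = 0.0385) were higher. Of the genes of this paragraph, Trf alone still passed without SCD1 inhibitor replicate 1 (adjusted p = 0.0101), and Chad alone without SCD1 inhibitor replicate 2 (adjusted p = 0.0158). The call of Neat1 ended also without DMSO replicate 2 (0.47, adjusted p = 0.0698). With the GC and length trend removed, the calls of Cyp2f2 (-0.56, adjusted p = 0.105) and Neat1 (0.77, adjusted p just over 0.05) ended.

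Of the tests below, that of the ciliated share and all 4 of the goblet cell list were chosen after the result was seen.

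More genes were higher than lower with the inhibitor, 188 against 59. With the GC content and transcript length trend removed, 31.4% of the 188 still passed, and the median log2 fold change of all 188 went from 0.79 (median SE 0.15) to 0.58 (0.14). The lower genes lost calls too: 39.0% of the 59 still passed, and they kept 91.0% of their median against 73.4% for the 188. After the correction 61 genes were higher and 27 lower at limma's adjusted p under 0.05. At an unadjusted p under 0.05 the counts were close, 798 higher and 731 lower. The trend between libraries may therefore account for part of the size of the higher values. More genes were still higher than lower, clearly so only among the adjusted calls. Most values became smaller, and some calls ended at about the same value and error through the adjustment over all genes. How much of the rest the trend explains stays open. A higher share of ciliated cells cannot be told apart. The ciliated list was higher (median 0.16; adjusted p = 0.573 with an estimated correlation) by less than the 188 genes, but these were picked by size. For a comparison free of that, the 188 genes highest in 1 library of each group were measured in the other 2 libraries. Their median lay above the upper quartile of the ciliated list in 5 of 8 cases, in all 4 splits of the libraries with a floor 10 times higher and in 1 of 4 with the floor for testing. The higher floor was tried first and the other after its outcome was seen, and the answer depended on the floor. With the floor for testing, genes picked against DMSO replicate 1 had medians of -0.013 and -0.13 in the other libraries. Such picks did not stay higher, so they cannot decide about the ciliated share. The splits also share libraries, so the cases are not independent. An effect of the inhibitor on the 188 genes stays open and was not tested beyond the comparison of 2 against 2 samples, and with limma 0 genes were higher without SCD1 inhibitor replicate 1 (574 at an unadjusted p under 0.05).

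Fatty acid synthesis genes were lower with the inhibitor (adjusted p = 0.451 with an estimated correlation). The GC and length trend is argued against, as 82.2% of the list's median was kept when it was removed. A lower share of alveolar type 2 and club cells could account for the list median of -0.32. It lay no further below 0 than the medians of the alveolar type 2 (-0.53) and club cell lists (-0.49). Both had camera's adjusted p = 0.573 with an estimated correlation. This cannot decide the question, since genes not particular to those cells can lie closer to 0 than markers for other reasons. Fasn, the 1 member that passed over all genes, had -0.76, below both medians, and the club cell marker Scgb1a1 had -0.23. The lower quartiles were -0.57 for the alveolar type 2 and -1.01 for the club cell list. Fasn was picked because it passed, so its place below the medians cannot count against a lower share of these cells. Reads from pooled sorted cells do not separate fewer lipid-producing cells from less transcript per cell, and a direct effect of SCD1 inhibition on lipid synthesis genes stays open as well.

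Goblet cell markers were lower with the inhibitor (adjusted p = 0.573 with an estimated correlation). The tables argue against the GC and length trend, as the list kept 103% of its median when it was removed, and against fewer airway cells of every type, as the lower quartile of the ciliated list, -0.016, lay above the upper quartile of the goblet list, -1.49, though the club cell list was lower (median -0.49, all 12 markers negative; adjusted p = 0.573 with an estimated correlation). Fewer cells from the airway parts that hold both goblet and basal cells could account for the lower goblet markers. The basal cell list was lower too (median -1.30, camera's adjusted p = 0.678 with an estimated correlation). Both lists put the 2 libraries of each group in the same order, which unrelated lists can also do by chance with so few libraries. Without SCD1 inhibitor replicate 1 the basal list had -0.56. A weaker IL-13 response of the whole epithelium cannot be told apart, because the 13 responsive genes that are not goblet markers went both ways, with a median of 0.034. A loss of goblet cells or of their mucus programme through the inhibitor stays open and was not tested.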
